A study of Mus musculus with 40 samples.

How the data were processed

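The deposited table is labelled by its name as TPM, a transcript abundance scaled by transcript length and library total. The submitters' processing notes name bcl2fastq, cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3, MultiQC 1.7 and the genome build GRCm38, without a role or an order for each. The gene annotation is not given in the sources used here. Libraries were made from poly(A)-selected RNA, per the labels' protocols.

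Samples were grouped by their titles, which were checked against the genotype, treatment and site in the other labels. The 40 value columns were all left unused, because a column was to be assigned by name alone. Their codes occur in 0 of the labels searched, and the search left out the entries that list each sample's deposited data. The planned analysis was a moderated linear model (limma) on log2(TPM + pseudocount) with Benjamini-Hochberg adjustment, and gene list tests on the same model. It was fixed before the data were examined and was not run. No depth per sample, counting interval or detection floor is given, because TPM values are scaled to a fixed total and keep no read counts.

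The header line and the gene names in the first column were read with Python 3.11.15. A gene name counted as matched when it was identical, letter case included, to a gene name of the GENCODE M21 comprehensive annotation, which is on the same build as the processing notes name. Types of gene were counted over matched names for which all entries of the annotation give 1 type. The names set to be reported in every comparison were Ucp1, Ppargc1a, Cidea, Adipoq, Lep, Agt, Agtr1a, Col1a1, Ccl2 and Cisd1. The other named genes were to be chosen by fold change and test results, and none were.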

Results

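The series measured polyadenylated RNA by paired-end sequencing in perivascular adipose tissue, the fat that surrounds the aorta, of C57BL/6J mice. The age of the mice was given as 8 to 12 weeks in all groups. It holds 40 samples in 12 groups, which cross 2 genotypes, 2 treatments and 3 stretches of the aorta. The genotypes were wild type, with 22 samples, and a line that expresses human mitoNEET from the mouse Ucp1 promoter, with 18 samples. MitoNEET is an iron-sulfur protein of the outer mitochondrial membrane, encoded in the mouse by Cisd1. Angiotensin II, a peptide hormone that constricts vessels and raises blood pressure, was given at 1000 ng/kg/min for 7 days by implanted minipump, and the control mice received saline. Fat was taken from around the ascending thoracic, the descending thoracic and the abdominal aorta. Wild-type groups had 4 samples each at both thoracic sites and 3 each at the abdominal site, and all 6 transgenic groups had 3.

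Each wild-type sample was RNA pooled from 2 to 3 mice, whereas each transgenic sample came from 1 mouse and was extracted with a different kit. A difference between the genotypes under saline could therefore not have been told apart from a difference in pooling or extraction in this design. For a genotype difference in the angiotensin II response, shifts from pooling and extraction would cancel only as far as they are additive on the log scale. A difference in spread between pooled and single-mouse samples would not cancel. The plan fitted both genotypes together for this contrast, with a shared estimate of the spread. The labels put the mean depth at 40000000 read pairs of 151 bp per sample. The depth of each sample is unknown, because TPM values are scaled to a fixed total.

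The plan held 19 comparisons, and 0 of them were run. They included angiotensin II against saline at each site in each genotype, and the 3 sites against each other under saline in each genotype. The plan also held the dependence of the angiotensin II response on site, in wild type only, and on genotype at each site. The genotypes under saline at each site completed it. The expression table names its 40 value columns by laboratory codes, and 0 of those codes occur in the labels of the samples or the series. That search left out the entries that list each sample's deposited data. The numbering of the codes does parallel the design. One code prefix stands on 22 columns and the other on 18, as many as the wild-type and the transgenic samples. The 22 codes form 6 runs of 4, 4, 3, 4, 4 and 3 columns, the sizes of the wild-type groups in the order in which the samples are listed. The runs start 12 codes apart except that code 69 is absent from the start of the third, and code 107 is absent within the sixth. In that order these places would fall to replicate 1 of the abdominal saline group and replicate 3 of the abdominal angiotensin II group, numbers that the titles of those groups also skip. Both thoracic sites had 4 wild-type samples under each treatment, so run sizes do not tell those sites apart. The 18 codes of the other prefix run from 1 to 18 without a gap, so their numbering marks no groups. This parallel rests on order and numbering, with no label that names a column, so it was not used to assign columns, and no expression level, fold change or p-value is given for any gene, site, treatment or genotype.

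The gene names show which genes the table lists. A row follows from the annotation used for quantification and does not show that the gene was expressed in this fat. The table has 55309 gene rows, of which 53543 (96.8%) carry a symbol found in the GENCODE M21 annotation of GRCm38. The other 1766 rows were not matched, and the annotation used for quantification is not given in the sources used here. The matched rows include 21706 protein-coding genes, 5223 long intergenic non-coding RNAs and 9343 processed pseudogenes. Of 36 gene lists fixed before the data were examined, 34 had a row for every member. All 22 genes of the brown adipocyte and thermogenesis list, all 46 nuclear-encoded genes of oxidative phosphorylation on the list used and all 13 protein-coding genes of mitochondrial DNA had a row. So did the 15 listed components of the renin-angiotensin system and the 28 listed Hox genes. The 2 symbols without a row, Ctgf and Cyr61, are older names, and Ctgf was listed beside its newer name, Ccn2, which had a row. For Cyr61, no row under a newer name is given here.

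The 10 genes set to be reported in every comparison each had 1 row and are protein-coding. Coordinates are on GRCm38, from GENCODE M21. Ucp1, the uncoupling protein of brown fat whose promoter drives the transgene, lies on chromosome 8 from 83290352 to 83298452. Agt, the angiotensin precursor, lies on the same chromosome from 124556534 to 124569706. Agtr1a, an angiotensin II receptor, lies on chromosome 13 from 30336441 to 30382867. Mouse Cisd1 lies on chromosome 10 from 71330480 to 71344954, and the human transgene was not analysed here. Ppargc1a, a coactivator of mitochondrial biogenesis, lies on chromosome 5 from 51454250 to 51567726, and Cidea, a lipid droplet protein abundant in brown fat, on chromosome 18 from 67343604 to 67367785. The adipokine genes Adipoq and Lep lie on chromosome 16 from 23146536 to 23158028 and on chromosome 6 from 29060220 to 29073877. Col1a1, a chain of type I collagen, and Ccl2, a monocyte chemokine, both lie on chromosome 11, from 94936224 to 94953042 and from 82035571 to 82037453. Their expression values were not used here.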

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

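No other setting fixed before the data were examined (pseudocount, low-value filter, rescaling, groups fitted, replicate block, left-out replicates, estimated correlation between genes) was run, since each needs columns matched to samples. No paired analysis was possible because the value columns carry no replicate number or sample name from the labels. The number of gene rows matched to the annotation was 53543 with the reference chromosomes and 53616 with the primary assembly annotation, an alternative chosen after seeing the data.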

Other observations

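The test in this part was chosen after the result was seen. The table has 26 rows whose gene name is a calendar date, 13 ending in Sep and 13 ending in Mar, and 2 of these names, 1-Mar and 2-Mar, each stand on 2 rows. A candidate explanation is spreadsheet conversion of gene symbols. The names on all 26 rows, 24 distinct names, equal the date form of an annotated septin (13 genes), March (11 genes) or Marc (2 genes) symbol, and 0 of those genes have a row under their own symbol. The March and Marc families give the same dates, so the 4 rows with a repeated name cannot be assigned to a gene by name.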
